A study of Mus musculus with 6 samples.

How the data were processed

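Total RNA of 6 kidney samples (3 CIH, 3 control), 0.5 µg each, was labelled with Cy3 and hybridised to circRNA arrays, per the labels. The labels also mention pancreatic tissue and a blood RNA kit with globin removal, which the kidney source does not explain. The group of each array rests on its title alone, and codes in the data files were not used for it.

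The deposited scanner files hold intensity values made by Agilent Feature Extraction, version 11.0.1.1 per the file headers, while the submitters' processing notes give version 9.1. The processed intensity is background-subtracted and detrended but not normalized between arrays, per the file headers. The authors' value table holds log2 values whose normalization is not given in the sources used here. Its columns rank as the spot median signal of the same array does (Spearman 0.9999 or above in every array), sorted columns nearly coincide, and the column medians are 7.57, 7.58 and 7.58 for CIH 1, 2 and 3 and 7.57, 7.57 and 7.58 for controls 1, 2 and 3. No centring of probes was seen in it. Above the lowest percent of values the sorted columns differed by at most 0.098, as quantile normalization would leave them, but the method is not stated.

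For each spot, log2 of the processed intensity minus the 75th percentile of the array over all non-control probes was used. Spots with an outlier flag were left out and replicate spots averaged. A circRNA probe was tested if it was well above background on at least 3 arrays and had at least 2 unflagged values per group. The first condition removed 0 probes and the second removed 9. CIH was compared with control by limma (lmFit and eBayes, version 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Array quality was compared by an exact two-sided permutation test of the difference of means over 20 assignments, whose smallest p is 0.1. The number of arrays limits the precision. Slide 1 held CIH 1, 2 and 3 and control 1, and slide 2 held controls 2 and 3, so slide and group are partly mixed. With slide as a block the difference is therefore estimated from CIH against control 1 alone, as in the fit on slide 1.

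The tests, the gene lists, the rule for named probes and most alternatives were fixed before the data were examined. That rule named circRNAs with an adjusted p under 0.05, filled up by smallest unadjusted p among probes with at least a 1.5-fold change and no overlap of groups. With no host gene names it takes at most 2 probes that rose and 2 that fell. The 50 linear RNA probes were added after the files had been seen. Of their accessions, 44 matched a gene symbol in the RefSeq gene table of the GRCm38.p6 assembly and 6 did not. That table was used for names only, and genome coordinates are not used here. Linear RNA probes were fitted in a limma model of their own.

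The alternatives tried were quantile normalization, normexp background correction (offset 50), median scaling, other filters, slide or replicate number as a block, other variance models, array weights, the authors' value table and leaving out each array. Normexp was planned on the mean spot signal, but the files hold the median spot signal, which was used in its place. Host gene lists, cell type markers and circRNA classes were not analysed here for circRNAs, because no table used here pairs the probes with genes or classes. The limma fit was tested on simulated data for this comparison, with 14227 probes of which 200 were changed. At 3 arrays per group it recovered 53.7% of probes changed 1.5-fold, 89.6% of those changed 2-fold and 93.9% of those changed 3-fold, with 13 false calls. The simulation had independent probes and no slide effect. Changes of 1.5-fold, 2-fold and 3-fold were adjusted together, so the 53.7% need not hold where all changes are 1.5-fold.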

Results

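Circular RNAs (circRNAs), closed RNA molecules formed by back-splicing, were measured by 1-colour microarray in kidneys of BALB/c mice. Chronic intermittent hypoxia (CIH) is a mouse model of obstructive sleep apnoea, in which breathing stops repeatedly during sleep. Oxygen in the cage was lowered to 6% for 60 seconds and returned to 21% for 60 seconds, 30 times per hour, 8 hours a day, for 8 weeks. The question was which circRNAs differ in the kidney after this exposure. There were 3 CIH and 3 control arrays, 1 per sample. The labels do not say that each array came from a separate mouse, so the p-values measure the spread between these samples, which may be technical. The array carried 14236 circRNA probes, named here by probe ID because no table used here gives their host genes, and 50 probes for linear RNAs, each spotted 10 times and named through an accession.

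Among the linear RNAs, 2 of the 50 probes passed the test, and both were lower in CIH kidneys. Acaa2, a mitochondrial thiolase that carries out the last step of fatty acid beta-oxidation, had a log2 fold change of -0.56 (SE 0.10, 95% interval -0.80 to -0.31). Gsta4, a glutathione transferase that detoxifies lipid peroxidation products, had a log2 fold change of -0.80 (SE 0.16, 95% interval -1.17 to -0.44). The limma adjusted p was 0.028 for each, and all 3 CIH arrays were below all 3 control arrays for both genes. The control mean of Acaa2 was 0.48 ± 0.18 (SD, n = 3) on the log2 scale relative to the array's 75th percentile, against a CIH mean of -0.07 ± 0.0593 (SD, n = 3). For Gsta4 the control mean was -0.99 ± 0.14 (SD, n = 3) and the CIH mean was -1.79 ± 0.30 (SD, n = 3). An exact two-sided permutation test gave p = 0.1 for each gene, the smallest value that 3 arrays against 3 allow. This set of probes was chosen for analysis after the files had been seen.

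The calls for Acaa2 and Gsta4 were lost in several other fits. With quantile normalization the log2 fold changes were -0.56 and -0.72 and the limma adjusted p 0.079 and 0.11. With slide as a block they were -0.38 and -0.95, with an adjusted p of 0.40 for both, and neither passed when fitted jointly with the circRNA probes (adjusted p 0.34). Within slide 1, which held the 3 CIH arrays and control 1, the CIH mean differed from control 1 by -0.38 for Acaa2 and -0.95 for Gsta4. Slide 2 held controls 2 and 3 and no CIH array. The estimate with slide as a block is therefore this same difference from control 1 alone. Leaving out control 2 ended both calls, leaving out CIH 3 ended that of Acaa2, and leaving out control 1 ended that of Gsta4. Without overlap between groups, only another scaling could have reversed the sign of either gene, and none did.

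Of the 25 gene lists fixed before the data were examined, 5 had a member among these linear RNAs. The lists were made for host genes of circRNAs, with at least 5 tested probes needed. Their use on linear RNAs was added later. In the mitochondria and fatty acid oxidation list, 1 of 3 measured members passed over all 50 probes. Adjusted over the list alone 2 passed (Acaa2 and Cpt1a), but that adjustment over 3 probes was not planned, and the Cpt1a groups overlapped. Cpt1a, which carries long-chain fatty acids into the mitochondrial import pathway, had a log2 fold change of -0.73 (SE 0.23, limma adjusted p 0.19). With slide as a block it was -0.35 (adjusted p 0.76), and control 1 at -0.74 lay within the CIH range of -1.38 to -0.70. Ppara, a nuclear receptor that controls fatty acid catabolism, had 0.12 (SE 0.13, adjusted p 0.71). In the oxidative stress and NRF2 list, Gsta4 passed, also when adjusted over the list alone, and Duox1, an NADPH oxidase, had 0.05 (SE 0.11). Atg3 of the autophagy list, E2f1 of the cell cycle list and Chgb of the pancreas list did not pass, with log2 fold changes of -0.07, -0.11 and 0.20. Each was the only measured member of its list, so adjustment over that list left its unadjusted p, and none passed.

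Outside the lists, Mbp, which encodes myelin basic protein, had a log2 fold change of 0.61 (SE 0.21) and Cav2, a caveolin, had -0.79 (SE 0.27), each with a limma adjusted p of 0.19. The Cav2 probe was dim, with a mean of -4.80 in CIH and -4.01 in control arrays. That is below the mean of the 15 probes named as negative, -3.51 in CIH and -3.27 in control arrays. Without CIH 2, Mbp (0.80), Cav2 (-1.03) and Cpt1a (-0.93) passed, each with an adjusted p of 0.015, and with the replicate number as a block Mbp and Cpt1a passed (0.041 for each), though the numbers were not taken as pairs. Mbp had 0.37 without CIH 1 and with normexp and the 75th percentile, while Cav2 had -0.18 with normexp and quantile normalization, -0.29 with normexp and the 75th percentile and -0.41 with slide as a block. Actb, which encodes cytoplasmic beta-actin, had -0.36 (SE 0.20, adjusted p 0.37), but -0.14 without control 3 and -0.12 with slide as a block, and Apoe, a lipid carrier, had -0.15 (SE 0.08, adjusted p 0.35). At an unadjusted p under 0.05 there were 9 linear RNA probes, 1 higher and 8 lower in CIH. That count was 3 without control 2, 5 without CIH 1 or without CIH 3, 13 without control 1, 5 with quantile or median scaling and 2 with slide as a block. The median SD of the 10 spots of a probe within an array was 0.037, against 0.11 between arrays of a group.

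**Figure D1:**
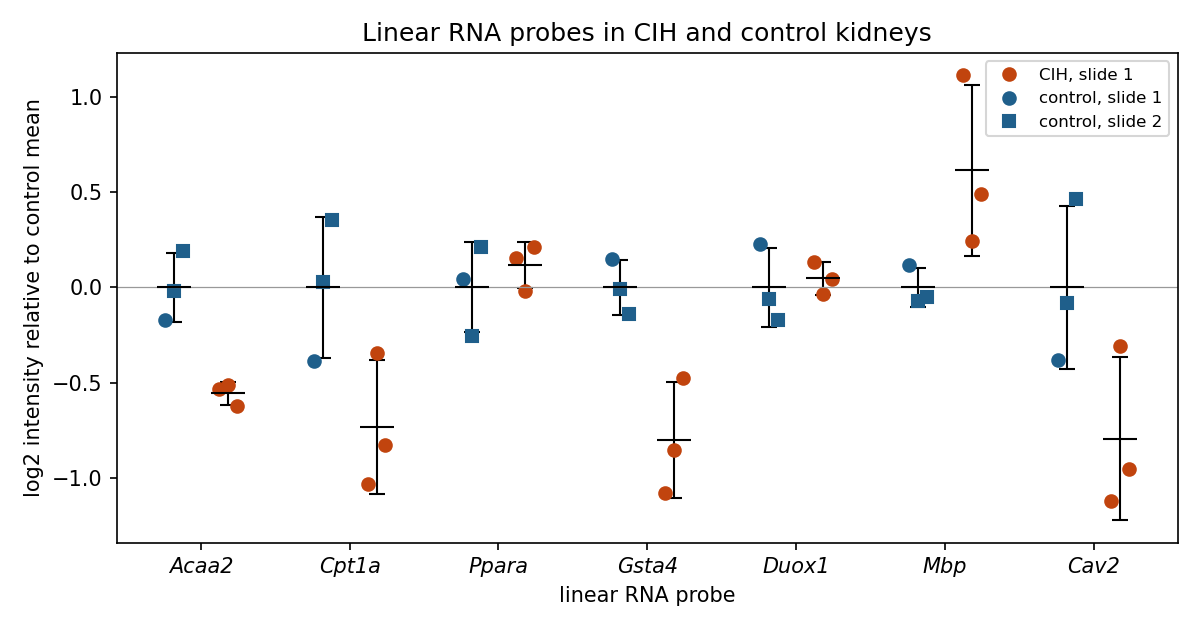
Log2 intensity of 7 linear RNA probes relative to each gene's control mean; points are arrays, circles slide 1 and squares slide 2, and bars show the group mean and SD (n = 3). For Acaa2 and Gsta4 the 3 CIH arrays lie below the 3 control arrays, with log2 fold changes of -0.56 and -0.80, and Cpt1a overlaps between groups.

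No circRNA passed the adjusted threshold. Of 14227 circRNA probes tested with limma, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.35. At an unadjusted p under 0.05 there were 1778 probes, 332 higher and 1446 lower in CIH, where 711 would be expected by chance from independent probes. This count was 734 without CIH 1, 1053 without CIH 3, 2869 without control 1 and 845 with slide as a block. The excess of lower probes depended on the scaling and on dim probes: there were 598 higher and 683 lower with quantile normalization, 742 and 756 with median scaling, and 228 and 211 among the 5206 probes above the 95th percentile of the negative-named spots on at least 3 arrays, a filter added after the data were seen. The percentile of this filter lay near the brightest of the 15 negative-named probes, at -0.67 in CIH 1 against a family mean of -3.61. Failing this filter therefore does not place a probe at the level of most negative-named spots. The median log2 fold change over all circRNA probes was -0.06, and -0.0011 with quantile normalization. The groups did not overlap for 17.6% of probes, against 10% by chance. For 98.0% of probes the 95% interval of the difference lay within 2-fold in either direction, and for 84.4% within 1.5-fold. At any p, 1 probe had a difference of at least 2-fold. These intervals bound the measured intensity and take no account of slide. The dimmest 2372 probes had a mean level of -3.65, against -3.51 in CIH and -3.27 in control arrays for the negative-named probes. For probes this dim, a narrow interval was not shown to bound the change of a circRNA.

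The threshold of an unadjusted p under 0.05 with at least a 1.5-fold change took 120 circRNA probes, 49 higher and 71 lower in CIH. The probes with the smallest p among those whose groups did not overlap were ASCRP4003150 and ASCRP4011816, higher in CIH by log2 fold changes of 0.70 (SE 0.13) and 0.59 (SE 0.11). On the lower side they were ASCRP4012074 and ASCRP4010022, with log2 fold changes of -0.61 (SE 0.10) and -0.59 (SE 0.10), but neither was above the negative-named spots by that filter. Their means were -3.80 in CIH and -3.18 in control for ASCRP4012074, and -4.94 and -4.35 for ASCRP4010022. These levels are near or below the mean of the negative-named probes, -3.51 in CIH and -3.27 in control arrays. None of these 4 circRNAs passed the adjusted threshold (limma adjusted p 0.35 for each). With the replicate number as a block all 4 passed (adjusted p 0.042 to 0.047), though the numbers were not taken as pairs. With slide as a block the adjusted p was 0.84 for each. As groups without overlap were required, only other scalings or the authors' value table could have reversed the sign of these 4, and none did. With normexp and quantile normalization, with normexp and the 75th percentile, and in the authors' value table the log2 fold change was -0.20, -0.31 and -0.32 for ASCRP4012074 and -0.10, -0.21 and -0.19 for ASCRP4010022. The direction of the set depended on the scaling, the background correction and the filter. It held 52 higher and 42 lower probes with quantile normalization and 96 and 32 with median scaling. With the 75th percentile kept it held 29 and 15 after normexp, and 40 and 21 above the negative-named spots. In the authors' value table it held 38 and 25. Leaving out CIH 1 gave 45 probes, leaving out CIH 2 gave 386 and leaving out control 1 gave 353, so single arrays set this count. With slide as a block the set held 159 probes, of which 30 were in the original set, and within slide 1 it held 181.

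The difference between groups depended on probe brightness. In the dimmest of 6 equal groups of circRNA probes the median log2 fold change was -0.16, with 88.7% of probes lower in CIH. In the brightest group it was 0.03. For the dimmest group the median difference of the CIH mean was -0.06 from control 1 on the same slide, -0.23 from control 2 and -0.18 from control 3.

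**Figure D2:**
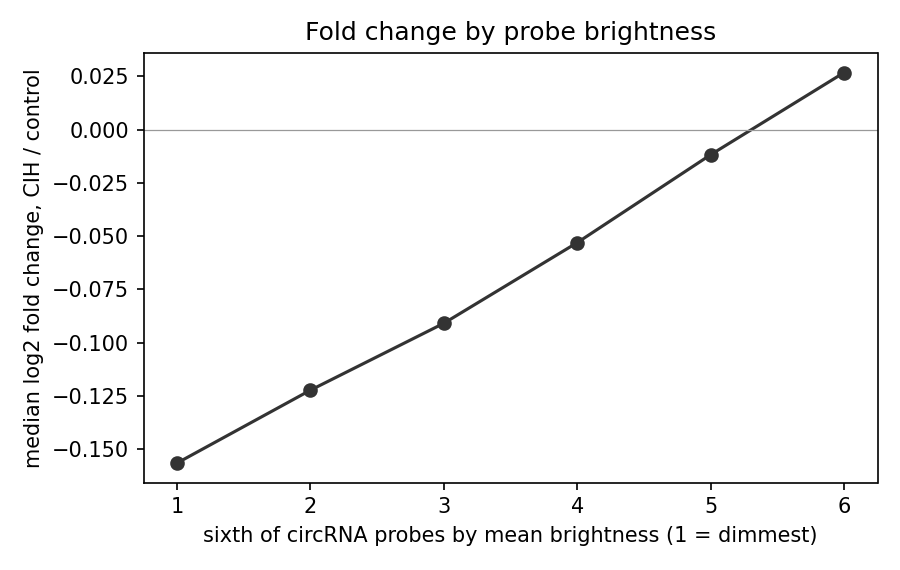
Median log2 fold change of CIH over control in 6 equal groups of circRNA probes ordered by mean brightness; each point is 1 group. The median goes from -0.16 in the dimmest group to 0.03 in the brightest.

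The flag for signal well above background was set on nearly every spot, so it could not show a difference in detection. The share of spots of non-control probes well above background was 99.97% ± 0.017 (SD, n = 3) in CIH and 99.99% ± 0.0038 (SD, n = 3) in control arrays (exact two-sided permutation p = 0.3). The 75th percentile of signal was 489 ± 33.8 (SD, n = 3) in CIH and 457.7 ± 10.002 (SD, n = 3) in control arrays (exact two-sided permutation p = 0.2), and no circRNA spot was saturated. Across circRNA probes within array pairs, which are not independent replicates, the Pearson correlation was 0.9925 to 0.9968 within CIH, 0.9902 to 0.9913 within control and 0.9861 to 0.9957 between groups. Control 1 correlated with the CIH arrays at 0.9924 to 0.9957, above its 0.9912 and 0.9913 with the other controls. Controls 2 and 3, on the other slide, also correlated more with CIH 2 (0.9946 and 0.9940) and CIH 3 (0.9920 and 0.9916) than with each other (0.9902), and CIH 2 had 0.9937 with control 1. The first principal component held 49.97% of the variance, with scores of -23.6, 1.80 and -8.99 for CIH 1, 2 and 3 and of -5.18, 17.89 and 18.04 for controls 1, 2 and 3.

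**Figure D3:**
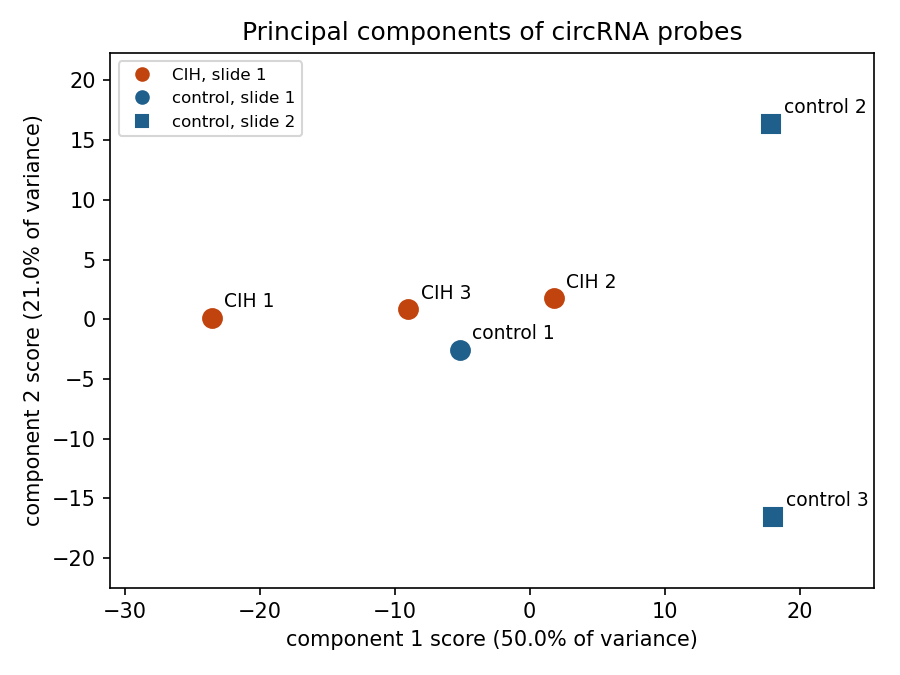
Scores of the 6 arrays on the first and second principal components of circRNA probes; colour gives the group, circles slide 1 and squares slide 2. Control 1, on slide 1, has a first component score of -5.18, between CIH 3 at -8.99 and CIH 2 at 1.80.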

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

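The 14 probes named as circRNA controls, which lay outside the main circRNA and linear RNA fits, had a higher mean in every CIH array than in any control array. The means were 0.49, 0.49 and 0.50 in CIH 1, 2 and 3 and 0.26, 0.16 and 0.42 in controls 1, 2 and 3, on the log2 scale relative to the 75th percentile. The difference was 0.21. This family was flagged because its CIH means lay above all control means. That choice alone sets the exact two-sided permutation p at 0.1, the smallest possible, so this p adds no support. The custom and the negative-named probes, both lower in CIH on average, also had an exact two-sided permutation p of 0.1. Of the 14 probes named as circRNA controls, 14 were higher in CIH, but they share the same 6 arrays. A separate limma model held these probes with the negative-named and custom probes. In it 0 of the 14 passed an adjusted p of 0.05 (smallest 0.067), and 5 had an unadjusted p under 0.05. The difference kept its sign under the 4 other scalings, from 0.19 to 0.29. The files do not say what these probes detect, and no explanation was tested.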

How the results depend on the processing

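The linear RNA set, the filter on negative-named spots, the 75th percentile over circRNA probes alone, the keeping of outlier spots and the fit on slide 1 were chosen after seeing the data. Host gene lists and circRNA classes were not run, nor were their alternatives. The count of circRNAs at an adjusted p under 0.05 was 0 in 22 of the 23 alternative fits, the range without 1 array being 0 to 0. With the replicate number as a block it was 118, and for linear RNAs the block gave 4. The deviations of same-numbered arrays correlated at 0.44, 0.29 and -0.07. The pair of number 3 was below the 0.1 needed in every pair, so the numbers were not taken as pairs. The background filter on 3 arrays removed no circRNA probe.

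The 120 circRNA probes of the 1.5-fold set became 36 with normexp and quantile normalization, 44 with normexp and the 75th percentile, 63 in the authors' value table, 52 in the ordinary linear model without moderation, 61 above the negative-named spots (5206 probes tested), 181 in slide 1 and 0 at 2-fold. Leaving out 1 array gave 45 (CIH 1) to 386 (CIH 2), with 353 without control 1. The estimate of array weights stopped before it converged. The 1778 probes at an unadjusted p under 0.05 became 1139 with normexp and quantile normalization, 845 with slide as a block, 2718 with the replicate block, 2793 with array weights and 439 above the negative-named spots. The 4 named circRNAs kept their sign under the other scalings. The 2 lower ones failed the negative-named filter and lost much fold with normexp or in the authors' value table. The detection difference of -0.015 percentage points lay between -0.022 and -0.0055 without 1 array and was -0.0022 with the other detection flag.

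The 2 linear RNA calls became 0 with quantile normalization, 0 with normexp and quantile normalization, 0 with slide as a block, 0 in slide 1, 0 when fitted jointly with circRNA probes and 0 without moderation. Leaving out 1 array gave 0 (control 2) to 5 (CIH 2), and 1 without CIH 3. Over the 17 alternatives adjusted p was 0.015 to 0.40 for Acaa2 and 0.0051 to 0.40 for Gsta4, and other scalings kept their sign. Slide 1 leaves 1 control array, assumed to vary as the others do.

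Some linear RNAs that did not pass changed sign. E2f1 had 0.028 with quantile normalization and 0.024 with normexp and quantile normalization. Atg3 had 0.055, 0.033 and 0.010 with quantile, normexp and quantile, and median scaling, and 0.058 with slide as a block and in slide 1. Chgb had -0.16 and Duox1 -0.18 with slide as a block and in slide 1. Leaving out 1 array gave Duox1 -0.038 (control 3) to 0.16 (control 1) and Ppara -0.011 (control 2) to 0.22 (control 3). The cause was not tested for these changes.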

Other observations

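The tests on slide for Acaa2 and Gsta4, on scaling and on dim probes, and the counts over splits of circRNA probes, were chosen after the result was seen, as was the reference with other arrays of slide 1 held out.

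Acaa2 and Gsta4 were lower in CIH. A shift that depends on brightness is argued against: the 500 circRNA probes nearest in brightness had a median log2 fold change of -0.035 on average over the 2 genes, against -0.56 and -0.80. With slide as a block the log2 fold changes were -0.38 for Acaa2 and -0.95 for Gsta4, and the larger adjusted p was 0.40. Between CIH at 0 and the controls of slide 2 at 1, control 1 lay at 0.60 for Acaa2 and 1.30 for Gsta4, not with the CIH arrays of its slide as slide alone would have it. Slide was still not excluded, since this rests on 1 array. Of the 10 splits of the 6 arrays, 1 gave as many linear RNA calls, the real one with 2, and the highest other gave 0. At an unadjusted limma p under 0.05 the real split gave 9 linear RNA probes. The split of CIH 1, CIH 3 and control 1 against the rest gave 10. In all, 10 splits are too few for a share under 0.05. An effect of CIH on these genes may remain as a hypothesis, and was not separated from slide.

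The arrays held a structure that the groups do not explain. CIH 1, CIH 3 and control 1 against the other 3 arrays gave 317 circRNA probes at 1.5-fold and an unadjusted p under 0.05, and 2513 at that p alone, against 120 and 1778 for the real split, and 2 of the 10 splits gave as many in each case. At the adjusted threshold all 10 splits gave 0. The 10 splits are too few for a share under 0.05. Scaling as the whole cause is argued against, since quantile normalization left 306 probes in that split and 94 in the real one. Slide stays open. On 477 probes picked without CIH 2, CIH 2 lay at a median position of 0.62 between slide 1 at 0 and slide 2 at 1, beyond the bound of 0.5 set in advance. By that bound the prediction for slide failed, but the bound left out the spread within slide 1. The same test put CIH 1 at -0.86, CIH 3 at 0.036 and control 1 at 0.30, all below 0.62. With control 1 held out, probes were picked on CIH against control arrays, so its 0.30 mixes slide and group. The first principal component parts the slides, at 1.80 or below against 17.89 or above. Slide was not excluded, since the position of CIH 2 rests on 1 array. No biological explanation was tested, as no label parts these arrays.

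Dim circRNA probes were lower in CIH, and 14 of the 15 probes named as negative were lower too, with a median log2 fold change of -0.23 (SD over probes 0.24). They differed from circRNA probes of the same brightness by a median of -0.066 (SD 0.24). A response of the arrays to dim signal, rather than circRNA levels, is a candidate explanation. A bootstrap over these probes gave the median log2 fold change of -0.23 an SE of 0.029, which treats the probes as independent. The explanation stays open, since the SD of single probes cannot judge a median and the negative-named probes share the same 6 arrays. Their mean was -3.61, -3.53 and -3.39 in CIH 1, 2 and 3 and -3.23, -3.21 and -3.36 in controls 1, 2 and 3 (exact two-sided permutation p = 0.1, the smallest possible). The mean difference was -0.25, and -0.10 with quantile normalization.

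The 15 unnamed custom probes had a mean difference of -0.12 between CIH and control, and -0.039 with median scaling. Of them 6 were higher in CIH, and 1 probe at -0.945 (SE 0.24) made up much of the mean.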
